A study of Danio rerio with 12 samples.

How the data were processed

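Gene-level read counts of 12 libraries were used, 3 biological replicates of entire larvae for each of 4 groups: exposed to tritiated water or control, at 7 or 10 dpf. Per the labels, eggs were collected 3 h after fertilization and larvae were kept at 28 °C in water with 60 mg/L of sea salt. Total RNA was extracted with TRIzol and chloroform without a DNase I step, and libraries were made with a stranded mRNA kit and read from both ends. The values are raw read counts per gene as deposited, which the submitters' processing notes describe as made with STAR on genome build GRCz11. The STAR version and the annotation release are not given in the sources used here. Each library has its own file with 32057 genes and 3 columns of counts, for reads without regard to strand and for either strand.

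The column of the strand opposite to read 1 was used, since the other strand held 2.24 to 2.55% of the reads on genes. The first lines of each file, which count reads outside genes, were left out. Of all reads, 65.5 to 68.4% were on genes, 14.4 to 14.8% mapped to several places, 4.56 to 5.43% did not map, 11.3 to 14.5% lay in no gene and 0.586 to 0.634% were ambiguous. Reads on genes ranged from 19.4 M to 67.3 M per library with a median of 44.4 M (M, 1e6), and the 10 most abundant genes took 7.92 to 9.82% of them. Symbols were taken from a table of gene IDs, which names 28988 of the 32057 genes. Some symbols are written in human style and are shared by paralogs: 1541 symbols stand for 3181 of the tested genes. Gene positions were not used here.

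Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 23075 genes, 21840 of them with a symbol. Counts were scaled with TMM and fitted with edgeR's robust quasi-likelihood model with 1 mean per group and 8 residual degrees of freedom. The comparisons were exposed against control larvae at 7 dpf and at 10 dpf, the difference between these effects, and 10 against 7 dpf in control and in exposed larvae. All tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. CPM per library were computed with TMM-scaled library sizes, and log2 CPM with a prior count of 2. In all, 37 lists of genes were written down, with 1751 symbols. Of these 1340 matched a gene exactly, 34 by a translated name and 308 by a stem, and 69 did not match. Lists were tested with limma's camera on voom values with a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the lists. Counts adjusted over the list alone come from the same gene tests.

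The genes named were those with the 12 largest rises and 12 largest falls among genes past the threshold at each age. Each needed all 3 exposed libraries above or below all 3 controls, a mean of at least 5 CPM in the higher group and a symbol that is no clone or locus name. The 5 genes with the smallest p, up to 4 members of each called list with the smallest p, and genes of the DNA damage response, of which cdkn1a and mdm2 are given, were added. Some genes and 1 list that these rules cover are not reported here. Between ages 6 genes per direction and 2 members per list were taken. For the difference these were the 5 smallest p among genes with a mean of at least 5 CPM in 1 group. The text says where a gene was chosen after its values were seen. An age position was computed for each library by projecting its log2 CPM on the change from 7 to 10 dpf averaged over control and exposed larvae, with the mean of both groups at 0 at 7 dpf and at 1 at 10 dpf.

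The alternatives were scaling with RLE or the upper quartile, no filter, a filter of 1 CPM in the 3 libraries of a group, the replicate number as a block, unstranded counts, a test against a fold of 1.5 (glmTreat), voom with sample weights, DESeq2, a fit of the compared groups alone, an age position from 500 genes, and leaving out each library in turn. A stratified exact test of the age position and thinning of all libraries to the shallowest were added after the results were seen. The methods were tested on simulated data with the group sizes and depths of these libraries. Of genes changed 2-fold, edgeR found 83.6% at 7 dpf, 66.7% at 10 dpf, 51.5% for the difference, 78.1% with age in controls and 68.7% with age in exposed larvae, with 4, 6, 8, 4 and 3 false calls. Of genes changed 1.5-fold it found 37.9%, 30.3%, 7.46%, 32.3% and 32.8% in the same order, so that changes of this size were mostly missed in the simulation. Each run changed 64 to 67 genes of each fold, and all genes were drawn independently. Far more genes were called at 10 dpf and with age in the real data, so these shares may not hold for those comparisons. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and matplotlib 3.10.9.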

Results

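The series title names the modes of action of tritium in early life stages of zebrafish as its subject. Messenger RNA was measured in entire larvae of Danio rerio (AB strain) that were exposed to tritiated water (HTO), water whose hydrogen is in part the radioactive isotope tritium, at a dose rate of 0.4 mGy/h, and in control larvae. Larvae were sampled at 7 and at 10 days post fertilization (dpf), which gives 4 groups of 3 biological replicates and 12 libraries. In the order of the replicates, exposed larvae gave 52.3 M, 60.0 M and 19.4 M reads on genes at 7 dpf and 28.6 M, 57.4 M and 40.03 M at 10 dpf (M, 1e6). Controls gave 67.3 M, 31.1 M and 35.8 M at 7 dpf and 52.7 M, 48.7 M and 32.0 M at 10 dpf. The exposed larvae stood in an incubator inside a glove box and the controls in an incubator outside it in the same room, so that exposure and incubator cannot be told apart in any comparison here. Values below are means of counts per 1e6 reads on genes (CPM) ± SD with n = 3 libraries per group, and log2 fold changes.

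Age and exposure both ordered the libraries. The leading principal component, with 44.0% of the variance, ran from 7 dpf to 10 dpf, and at each age the 3 exposed libraries lay on its younger side of the 3 controls. Exposed libraries at 10 dpf scored between 5.44 and 17.53, against 56.98 to 63.52 in the controls of that age. At 7 dpf, control replicate 3, at -33.97, lay nearest to the exposed libraries. The next component, with 21.2%, set exposed replicate 1 at 10 dpf apart, at 79.7 against -33.82 to 24.79 in the other libraries. Replicates of a group correlated with Pearson's r of 0.972 to 0.993 across genes, which are not independent replicates, and the lowest values were those of exposed replicate 1 at 10 dpf.

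**Figure D1:**
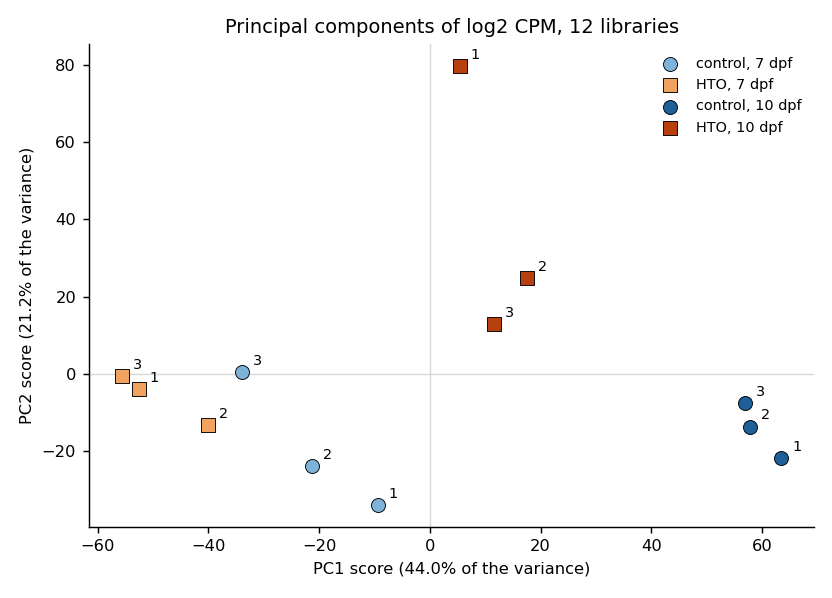
Scores of the 12 libraries on the first principal components of log2 CPM, circles for control and squares for exposed (HTO) larvae, light for 7 dpf and dark for 10 dpf, with the replicate number beside each point. Exposed replicate 1 at 10 dpf sits at 79.7 on the vertical axis, above all other libraries.

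The comparison of exposed with control larvae at 7 dpf asks which transcripts had changed by that age. Among the genes that fell were EHF (ENSDARG00000052115) and ELF3 (ENSDARG00000077982), both epithelial transcription factors of the ETS family. EHF fell from 6.90 ± 3.72 to 0.744 ± 0.182 CPM (log2 fold change -3.18, adjusted p = 0.0241) and ELF3 from 52.2 ± 18.4 to 12.1 ± 2.19 CPM (-2.12, adjusted p = 0.0116). Members of the fixed inflammation list fell too, among them the chemokine cxcl18b (-1.82), the cytokine feedback inhibitor SOCS3 (-1.09) and the AP-1 subunit JUNB (-0.95). MPEG1 (ENSDARG00000043093), which encodes a pore protein of macrophages, fell from 41.7 ± 8.80 to 17.5 ± 3.31 CPM. Among the rises, the epithelial calcium channel TRPV6 (ENSDARG00000014496) went from 19.6 ± 2.14 to 44.9 ± 9.78 CPM (1.195 on the log2 scale, adjusted p = 0.00779).

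Of 23075 genes tested at 7 dpf, 119 passed the test, 41 higher and 78 lower in exposed larvae, and 54 of these changed by over 2-fold, 6 upward and 48 downward. Among the rises named by the rule were fthl29, of the ferritin heavy chain family (1.38), and 4 genes that carry the symbol KCNJ1, an inwardly rectifying potassium channel (1.196 for ENSDARG00000090866, 1.03 for ENSDARG00000090635, 0.95 for ENSDARG00000088484 and 0.92 for ENSDARG00000086248). They also included xkr8.2 (0.96), nr1d4a of the Rev-erb family of clock repressors (0.83), the glutamate transporter slc1a8b (0.79), the kinase nim1kb (0.79), the pteridine pigment enzyme gch2 (0.75) and cyp11c1, an enzyme of cortisol synthesis (0.74). Among the falls were those of the sulfotransferase sult5a1 (-2.19), fasn2 (-1.89), the fast muscle myosin heavy chain myhb (-1.27, from 86.8 to 36.1 CPM), UNC93A (-1.02), the claudin cldnf (-1.01) and arid6 (-0.99). By p, si:ch73-335l21.4 (ENSDARG00000091234, -1.19, adjusted p = 0.00339) and ahrra (ENSDARG00000099702), the repressor of the aryl hydrocarbon receptor (-1.65, adjusted p = 0.00509), led the list. The DNA damage response genes mdm2 (0.11, adjusted p = 0.738) and cdkn1a (0.34, adjusted p = 0.321) did not pass, and other genes of that response are not all reported here. In 3865 genes (16.7%) the 3 exposed and the 3 control libraries did not overlap, where chance gives 10% on average over splits. Genes move together, so a single split can lie above that by chance, and the share was not tested. The count of 119 rests on single libraries: it was 22, 35 and 35 without exposed replicates 1, 2 and 3, and 12, 18 and 831 without control replicates 1, 2 and 3. Of the 40 named genes that passed at 7 dpf, si:ch73-335l21.4, ahrra, myhb, nr1d4a, nim1kb, SOCS3 and TRPV6 kept their call whichever library was left out. Among the 40, 32 lost it without control replicate 1, 28 without control replicate 2, and 28, 22 and 19 without exposed replicates 1, 2 and 3.

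The gene lists, fixed before the data were examined like the tests and the rule for named genes, were tested next at 7 dpf. Of 49 inflammation and acute phase genes, 7 fell, 21 when adjusted over the list alone, with a median of -0.50 (camera adjusted p = 7.78e-12, adjusted p = 0.327 with an estimated correlation). The count of 7 was 1 without exposed replicate 1 or control replicate 2, 3 without control replicate 1 and 15 without control replicate 3. The 7 were SOCS3, JUNB, JUN (-0.39), cxcl18b, the chemokines ccl34a.4 (-1.44) and ccl20a.3 (-2.23), and the anti-inflammatory cytokine IL10 (-2.76). Of 38 macrophage and neutrophil genes MPEG1 fell (edgeR adjusted p = 0.0458). The list as a whole was lower (camera adjusted p = 4.95e-06, 0.652 with an estimated correlation). Of 43 interferon response genes no member passed over all genes and 3 fell adjusted over the list alone, at a median of -0.47 (adjusted p = 2.32e-07, 0.597 with an estimated correlation). The interferon call was lost without control replicate 1 (adjusted p = 0.0599), while 5 members fell over all genes without control replicate 3. In the mean log2 CPM of that list relative to all libraries exposed replicate 3 (0.151) lay above control replicates 2 and 3 (-0.079 and -0.427), and in those of macrophages exposed replicate 2 (-0.2) lay above control replicate 3 (-0.311). Values of irf1a (-3.00, adjusted p = 0.129) and PSMB9 (-1.33, adjusted p = 0.081) stand for that list. Ribosome biogenesis (median -0.17, adjusted p = 1.37e-09), proteasome (-0.15, adjusted p = 1.12e-08) and heat shock genes (-0.26, adjusted p = 2.26e-07) were lower as lists, each with adjusted p = 0.597 with an estimated correlation. Of these, 1 proteasome and 1 heat shock gene fell adjusted over the list alone, and 1 and 13 over all genes without control replicate 3. In the mean of the heat shock list control replicate 3 (-0.251) lay below all exposed libraries (-0.226 to -0.176), and control replicate 1 stood at 0.6. In the macrophage list 3 genes fell without control replicate 3, and 0 without control replicates 1 and 2 or exposed replicates 1 and 3. Cholesterol synthesis genes were lower too (-0.17, adjusted p = 0.00681, 0.716 with an estimated correlation), a call lost without exposed replicate 1 (adjusted p = 0.126) and control replicate 1 (adjusted p = 0.236).

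Lists that were higher at 7 dpf were led by phototransduction, whose 72 genes had a median of 0.24 (camera adjusted p = 6.94e-17, adjusted p = 0.327 with an estimated correlation). The exchanger slc24a2, which is known from cones, rose (0.64), and 18 genes rose and 1 fell adjusted over the list alone. Pigment cell genes (gch2 rose, 6 of 34 adjusted over the list alone, median 0.17, adjusted p = 4.76e-09) and clock genes (nr1d4a rose, 5 of 51 adjusted over the list alone, 0.12, adjusted p = 4.46e-06) each had adjusted p = 0.174 with an estimated correlation. These 2 lists also passed fry (adjusted p = 0.0235 each), which tests whether the genes of a list move on balance in 1 direction and compares them with no other gene. Fast muscle (0.12, adjusted p = 1.71e-06, 0.597 with an estimated correlation) was higher as a list while its member myhb fell, and 2 members rose and 4 fell adjusted over the list alone. Cartilage, bone and collagen (0.16, adjusted p = 4.21e-05, 0.597), nuclear oxidative phosphorylation genes (0.09, adjusted p = 1.95e-05, 0.716) and lens crystallins (0.09, adjusted p = 0.000287, 0.716) had no member that passed, the last p of each with an estimated correlation. In the epidermis and ionocyte list (0.11, adjusted p = 0.000257, 0.327 with an estimated correlation) TRPV6 rose, with 3 rises and 2 falls adjusted over the list alone. In the list of stress and thyroid hormone axes (0.03, adjusted p = 0.0333, 0.597 with an estimated correlation) cyp11c1 and smtlb, the pituitary hormone somatolactin beta, rose (0.74 and 1.59). The hormone list was not called without exposed replicate 1 (adjusted p = 0.0814) or control replicate 1 (adjusted p = 0.262). DNA replication (0.19, adjusted p = 2.94e-06, 0.652 with an estimated correlation) and erythroid genes (0.12, adjusted p = 0.0177, 0.652) lost their calls without control replicate 3 (adjusted p = 0.28 and 0.259). Myogenesis (0.05, adjusted p = 0.0141, 0.597) was not called without exposed replicates 1 and 2 or control replicate 3 (adjusted p = 0.0652, 0.0551 and 0.0612). Fatty acid oxidation (0.05, adjusted p = 0.0156, 0.729) was not called without exposed replicate 1 or control replicate 3 (adjusted p = 0.126 and 0.0814). Without control replicate 3 the rises over all genes were 8 in epidermis, 7 in phototransduction and 4 in the clock list, where all libraries gave 1 each, and phototransduction had 0 when any other library of that age was left out. In their list means exposed and control libraries did not overlap for inflammation, phototransduction, clock, pigment cell and erythroid genes, and they overlapped for every other list called at 7 dpf.

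The other lists reported here were not called at 7 dpf. Of stress and damage responses these were DNA repair (median 0.00, adjusted p = 0.523), apoptosis (-0.12, adjusted p = 0.142), the antioxidant response (-0.03, adjusted p = 0.88), hypoxia (adjusted p = 0.523) and the xenobiotic response (adjusted p = 0.523). Of tissues they were slow and cardiac muscle (adjusted p = 0.464), pancreas enzymes (0.19, adjusted p = 0.356), liver (0.07, adjusted p = 0.236), intestine (adjusted p = 0.88), yolk (adjusted p = 0.523), neurons (adjusted p = 0.289) and myelin and glia (adjusted p = 0.356). The rest were fatty acid synthesis (adjusted p = 0.889), the mitochondrial genome (adjusted p = 0.889), ribosomal proteins (0.03, adjusted p = 0.0697) and chromatin enzymes (adjusted p = 0.0844). Among their members the glutamate transporter SLC1A2 (0.54), the glial fatty acid binding protein FABP7 (0.37) and ahrra passed. The intestine list had a median of 0.05 with a camera direction of down, and the neuron and fatty acid synthesis lists had medians below 0 with a direction of up. Calls of 6 of these lists depended on single libraries or on scaling. DNA repair (adjusted p = 0.0398) and hypoxia (0.0447) were called without control replicate 1, apoptosis without exposed replicate 2 (0.0319) or control replicate 3 (0.00637), and neurons without the same libraries (0.00131 and 0.0112). Chromatin enzymes were called without exposed replicate 2 (0.00138), and ribosomal proteins without exposed replicates 1 and 3 or control replicate 1 (0.0033, 0.00119 and 0.0116). Ribosomal proteins were also called with RLE (0.0404) and upper quartile scaling (0.0443), and chromatin enzymes with RLE (0.0487).

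At 10 dpf single genes known from cone photoreceptors were higher in exposed larvae, and single genes of macrophages and of cell division were lower. The cone arrestin ARR3 (ENSDARG00000098475) rose from 66.0 ± 15.1 to 199 ± 8.75 CPM (log2 fold change 1.59, adjusted p = 8.87e-05), the cone opsin kinase GRK7 (ENSDARG00000020602) by 1.195 and the cone opsin OPN1SW (ENSDARG00000045677) by 1.03. MFAP4 (ENSDARG00000038683), a marker of macrophages in zebrafish, fell from 11.02 to 1.82 CPM (-2.60, adjusted p = 0.00106), and MPEG1 fell by 1.01. The proliferation marker mki67 (ENSDARG00000091150) fell from 22.2 to 11.5 CPM (-0.94, adjusted p = 0.000812) and the mitotic kinesin kif11 by 1.47. The fall of MPEG1 was not called without control replicate 1 (adjusted p = 0.0597).

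In all, 2721 genes passed at 10 dpf, 1101 higher and 1620 lower, with a median change of 0.56 on the log2 scale among them, and 64 rises and 553 falls were over 2-fold. Among the rises named by the rule were those of ponzr3 (2.82) and ponzr4 (ENSDARG00000087440, 3.47, from 0.379 to 4.21 CPM), both of the onzin-related family, and of the type I keratins cyt1l (2.41, from 34.7 to 184 CPM) and cyt1 (1.28). The others included gvin1l2 (2.17), the aerolysin-like protein aep1 (1.65), the photoreceptor gene SAMD7 (1.46), cbln18 (1.403), the mitochondrial creatine kinase CKMT2 (1.28), rtn2b (1.25) and gch2 (1.25, from 7.44 to 17.6 CPM). Among the falls were those of lgals9l4, of the galectin family, with 2, 3 and 3 reads in the exposed libraries against 2550, 1449 and 108 in the controls, and rnasel4, with 0, 4 and 3 against 694, 1470 and 186. Others were those of the ATP-gated channel P2RX4 (-5.87), the myosin heavy chain MYH11 (-5.38, from 84.7 ± 54.8 to 2.03 CPM), the jacalin genes jac7 (-3.80) and jac1 (-2.86), and the interferon regulatory factor irf1a (-3.18). Further ones were the MHC class I gene mhc1lla (-2.97), the kinase BTK of immune cells (-2.79), EHF (-2.77), ifi27.2 (-2.72) and vwa10.1 (-2.67). By p, sult1st7 (-3.51) and the lysosomal fucosidase FUCA1 (ENSDARG00000035890, -1.36, from 202 to 78.7 CPM, adjusted p = 1.83e-05) also led. The DNA damage response genes mdm2 (-0.08, adjusted p = 0.618) and cdkn1a (0.01, adjusted p = 0.977) did not pass, which says nothing of the genes not reported here. The exposed and control libraries did not overlap in 7801 genes (33.8%, by chance 10% on average over splits), a share that was not tested either. The count fell to 1533 without exposed replicate 1, with 1382 of the 2721 genes among them, and to 1153 and 1540 without control replicates 1 and 2. Of the 115 named genes that passed, 80 kept their call whichever library was left out. Here cyt1 lost it without control replicate 1 (adjusted p = 0.0511), irf1a without any exposed replicate or control replicate 1 (up to 0.0719). The same held for mhc1lla without exposed replicates 1 and 3 or control replicates 1 and 2 (up to 0.0597), and vwa10.1 without exposed replicates 1 and 2 or control replicate 1 (up to 0.0692).

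Camera called 10 lists as higher at 10 dpf, and 0 of them with an estimated correlation. Of 72 phototransduction genes 34 rose, 40 adjusted over the list alone (median 0.43, camera adjusted p = 1.01e-18, adjusted p = 0.448 with an estimated correlation), with both ARR3 genes (1.59 and 0.94) among them. Of 63 lens genes 26 rose, 41 adjusted over the list alone (0.34, adjusted p = 6.09e-15, 0.461 with an estimated correlation), such as crygm2e (0.76) and the water channel MIP (0.59). Neurons gained in 20 of 65 genes, 33 adjusted over the list alone (0.26, adjusted p = 6.09e-15, 0.461 with an estimated correlation), with the neurofilament gene INA (0.84) and the GABA transporter SLC32A1 (0.70). Cartilage, bone and collagen rose in 17 of 60 genes, with 25 rises and 1 fall adjusted over the list alone (0.31, adjusted p = 2.69e-07, 0.461 with an estimated correlation), among them COL11A1 (0.67). Myelin and glia rose in 7 of 32, the same number adjusted over the list alone (0.20, adjusted p = 0.000175, 0.227 with an estimated correlation), with FABP7 (0.55) among them. In fast muscle 16 rose and 2 fell, 24 and 4 adjusted over the list alone (0.12, adjusted p = 1.51e-05, 0.591 with an estimated correlation), with MYOZ1 (0.64) and the calcium buffer pvalb1 (0.47). Without exposed replicate 1, each of these lists was still called, but fewer members passed: 26 in phototransduction, 8 in lens, 10 in neurons, 6 in cartilage, 5 in myelin, and 14 rises in fast muscle. The lowest counts in runs that left out a library were 25, 7 and 1 for phototransduction, neurons and cartilage without control replicate 1. They were 7 for lens without control replicate 3, 2 for myelin without control replicate 2 and 9 rises for fast muscle without exposed replicate 3. In the list of stress and thyroid hormone axes smtlb (1.82), the appetite peptide gene NPY (0.59) and the thyroid hormone receptor THRB (0.51) rose, 3 adjusted over the list alone (0.17, adjusted p = 0.0183, 0.461 with an estimated correlation). That call was lost without exposed replicate 3 (adjusted p = 0.12) or control replicate 3 (0.0816). The number of members that rose also depended on the libraries and was 5 without exposed replicate 1.

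The clock list was higher at 10 dpf, with 15 of its 51 genes up and 2 down, 25 and 3 adjusted over the list alone. The rises were down to 9 without control replicate 2. Its median was 0.20 (camera adjusted p = 3.52e-06, adjusted p = 0.227 with an estimated correlation, fry adjusted p = 0.00212). PER1 (ENSDARG00000012499), a clock repressor, rose from 148 to 247 CPM (0.74, adjusted p = 0.000746), and CRY1 (0.39), CRY2 (0.49) and ciarta (0.60) rose as well. Pigment cell genes were higher (0.09, adjusted p = 0.032, 0.591 with an estimated correlation), with rises of gch2, pnp4a (0.74) and ATIC (0.34), both of purine metabolism, and 2 rises adjusted over the list alone. That call was lost without exposed replicates 1 and 3 (adjusted p = 0.0782 and 0.0968) or control replicates 1 and 2 (0.0577 and 0.0878). ATIC passed only without exposed replicate 1 and with all libraries, with adjusted p of 0.065 to 0.138 without each of the others. Myogenesis genes went both ways, with 6 up and 5 down, 13 and 5 adjusted over the list alone (0.14, adjusted p = 0.0498, 0.591 with an estimated correlation): the atrophy ligase FBXO32 (-0.63) and the cathepsins CTSB (-0.64) and CTSD (-0.40) fell. Without exposed replicates 1 and 3 or control replicate 1 this list was not called (adjusted p = 0.063, 0.12 and 0.132), nor with the stricter filter (0.0743), and its rises were 2, 4 and 0 without these libraries.

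Camera called 12 lists as lower at 10 dpf, and 0 of them with an estimated correlation. Of 43 interferon response genes 18 fell, 27 adjusted over the list alone, with a median of -1.13 (camera adjusted p = 6.51e-12, adjusted p = 0.461 with an estimated correlation). They included the antiviral gene ifit9 (-3.34), the immunoproteasome subunit PSMB9 (-1.32) and the signal transducer stat2 (-0.48, from 31.3 to 22.4 CPM). In the macrophage and neutrophil list 5 of 38 fell, the same number adjusted over the list alone (-0.37, adjusted p = 2.43e-05, 0.621 with an estimated correlation). These were MFAP4, MPEG1, LECT2 (-0.90), CORO1A (-0.65) and the leukocyte phosphatase ptprc (-0.63), of which CORO1A was named after its value was seen. Inflammation genes as a list were not called (-0.23, adjusted p = 0.288), with 3 falls, of nfkb1 (-0.64), nfkb2 (-0.56) and ccl20a.3 (-1.10), and 4 rises, of ptgdsb.2 (0.84), JUNB (0.84), FOSB (0.71) and JUN (0.25), all named after their values were seen. Proteasome genes fell in 24 of 40 cases, 34 adjusted over the list alone (-0.35, adjusted p = 2.33e-14, 0.461 with an estimated correlation), with PSME4 (-0.75, from 227 to 135 CPM) and psmd4b (-0.43). DNA replication and cell division genes fell in 21 of 57 cases, 32 adjusted over the list alone (-0.67, adjusted p = 3.88e-12, 0.48 with an estimated correlation), with kif11, mki67, TPX2 (-1.03) and CDC20 (-0.88). Ribosome biogenesis (-0.20, adjusted p = 1.03e-05, 0.621 with an estimated correlation) held 5 falls and 2 rises, the same numbers adjusted over the list alone. UTP20 (-0.31), ddx10 (-0.32), POLR1A (-0.30), POLR1B (-0.38) and MPHOSPH10 (-0.33) fell, and MYC (0.28) and mych (0.32) rose. The counts of falls were lower without exposed replicate 1, with 7 for the interferon list, 2 for macrophages, 8 for the proteasome, 18 for DNA replication and 0 for ribosome biogenesis. Without control replicate 1 they were 4, 1, 2, 13 and 0, and without exposed replicate 3 macrophages had 8. Inflammation had 1 fall and 2 rises without exposed replicate 2 or any control replicate. Of the genes here that the rule named, MPEG1 lost its call without control replicate 1 (adjusted p = 0.0597), and ptprc without exposed replicate 1 or control replicate 1 (up to 0.1). LECT2 lost its call without exposed replicates 1 and 2 or control replicates 1 and 3 (up to 0.167), and UTP20 without exposed replicate 1 or control replicate 1 (0.0653 and 0.0664). The call of mych was lost without exposed replicates 1 and 3 or control replicate 2 (up to 0.0933), and that of ddx10 without exposed replicates 1 and 3 or control replicates 1 and 2 (up to 0.125). JUN kept its call in none of the 6 runs that left out a library (up to 0.136 without control replicate 1), and ccl20a.3 only in that without exposed replicate 3 (up to 0.105 without control replicate 1).

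The digestive organ lists were lower at 10 dpf in 1 library of the group. Liver (median -0.44, camera adjusted p = 0.000327, adjusted p = 0.709 with an estimated correlation) and exocrine pancreas genes (-0.45, adjusted p = 0.000368, 0.64 with an estimated correlation) had no member that passed, over all genes or over the list alone. Values of apoa1b (-0.80, adjusted p = 0.381) and cuzd1.1 (-0.73, adjusted p = 0.0509) stand for them. In exposed replicate 1 the pancreas list lay at -2.82, the liver list at -2.39 and the intestine list at -1.13 of mean log2 difference from the other exposed libraries, and 74.2% of the 124 members were over 2-fold lower. Without that library the pancreas list had adjusted p = 0.895, and the liver and intestine lists were not called, with a direction of up (0.594 and 0.474). The intestine list (-0.28, adjusted p = 0.0343, 0.698 with an estimated correlation) held falls of the lysosomal protease CTSZ (-0.71) and of AGR2 (-1.41) and rises of FABP6 (0.71), CUBN (0.49) and dab2 (0.40), the same numbers adjusted over the list alone. CUBN was named after its value was seen. It was not called without control replicates 2 and 3 either (adjusted p = 0.0878 and 0.0816). AGR2 and dab2 each kept their call in 1 of the 6 runs that left out a library, with adjusted p up to 0.136 without control replicate 1 and up to 0.0788 without exposed replicate 1. Yolk genes (-0.47, adjusted p = 0.032, 0.621 with an estimated correlation) held falls of CTSD and ctsla (-0.50) and a rise of serpinf1 (0.49), the same numbers adjusted over the list alone. They lost their call without exposed replicate 1 (0.357) or control replicate 2 (0.0636), and ctsla lost its own without exposed replicate 1 or control replicates 1 and 2 (up to 0.0953). Without exposed replicate 1, calls of the following lists were lost too: the antioxidant response (adjusted p = 0.00424 with it and 0.275 without it), apoptosis (0.00876 and 0.0502) and heat shock (0.0183 and 0.0807).

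**Figure D2:**
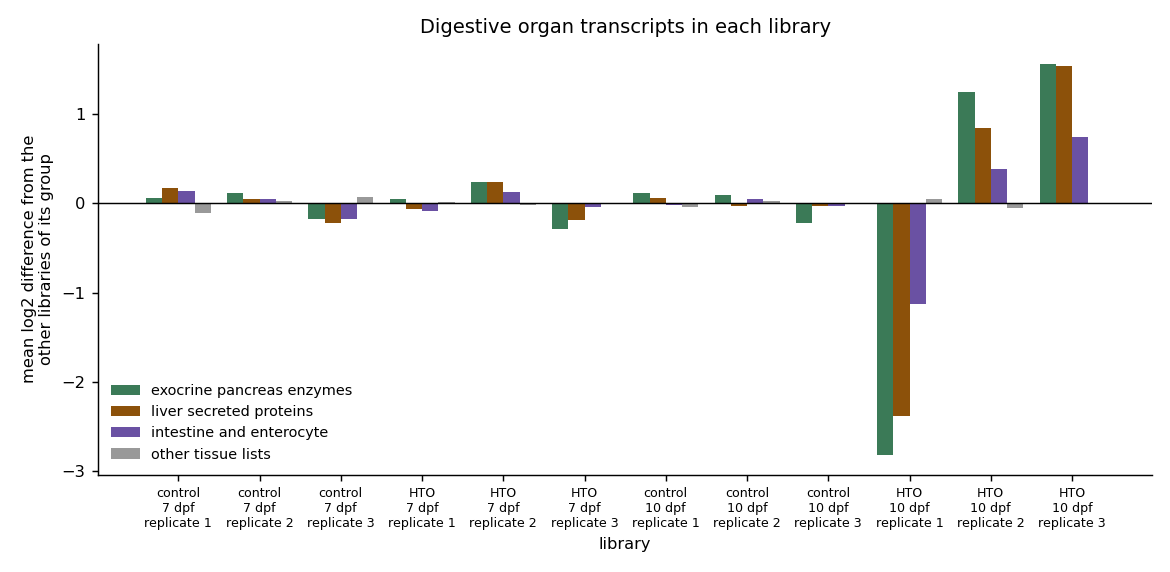
Mean log2 difference of each library from the other libraries of its group over the members of 3 digestive organ lists and of muscle, neuron, photoreceptor, skeleton and epidermis lists (other tissue lists). Exposed replicate 1 at 10 dpf lies at -2.82, -2.39 and -1.13 for pancreas, liver and intestine and at 0.045 for the other tissue lists.

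In these last lists single genes changed in stress pathways at 10 dpf. Of 51 antioxidant genes 7 fell and 1 rose, 8 and 1 adjusted over the list alone (median -0.14, adjusted p = 0.621 with an estimated correlation), with glutathione reductase GSR (-0.44), NQO1 (-0.56), keap1a (-0.41) and the regulator NFE2L2 (-0.41) lower. Of 52 heat shock and unfolded protein genes 5 fell and 1 rose, 4 and 1 adjusted over the list alone (-0.15, 0.714 with an estimated correlation). HERPUD1 (-0.60), ASNS (-0.65), MANF (-1.32), CRELD2 (-1.27) and dnaja1 (-0.32) fell, and the small heat shock protein CRYAB (2.42), which is also a lens crystallin, rose. Of 29 apoptosis genes casp8 (-0.65), bik (-0.62) and bida (-0.57) were among those that fell and the survival factor BCL2L1 (0.22) rose, with 6 falls and 1 rise adjusted over the list alone (-0.20, 0.621 with an estimated correlation). CRELD2 and dnaja1 were named after their values were seen. Without exposed replicate 1 or control replicate 1 only 2 antioxidant and 2 heat shock genes fell. No apoptosis gene passed without exposed replicates 1 and 2 or control replicates 1 and 2. GSR, HERPUD1, ASNS and CRYAB kept their calls whichever library was left out. The highest adjusted p of the others was reached without control replicate 1 for bik (0.11), bida (0.126), casp8 (0.134), NFE2L2 (0.109) and MANF (0.0885), and without control replicate 2 for NQO1 (0.0721), keap1a (0.0692) and BCL2L1 (0.116). Leaving out exposed replicate 1 also ended the calls of these genes except NQO1, exposed replicate 2 those of NFE2L2, bik, bida, casp8 and BCL2L1, and exposed replicate 3 those of bik and casp8. Leaving out control replicate 2 ended those of bik, bida, casp8 and MANF, control replicate 1 those of NQO1 and BCL2L1, and control replicate 3 those of casp8, MANF and BCL2L1.

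Beside inflammation, the remaining lists reported here were not called at 10 dpf. Their adjusted p were 0.0922 for DNA repair, 0.0905 for hypoxia, 0.0949 for slow and cardiac muscle, 0.839 for cholesterol synthesis, and 0.43 for fatty acid synthesis. They were 0.156 for fatty acid oxidation, 0.288 for nuclear oxidative phosphorylation genes, 0.206 for the mitochondrial genome, 0.311 for ribosomal proteins, 0.099 for the xenobiotic response, 0.839 for erythroid genes, 0.0979 for epidermis and 0.432 for chromatin enzymes. Single members passed, named after their values were seen. Of DNA repair genes the recombination gene RAD54L (-0.84) and the end joining gene XRCC5 (-0.37) were among those that fell. Of 45 epidermis genes 14 rose and 7 fell, 17 and 9 adjusted over the list alone, and 8 and 5 over all genes without control replicate 1. Hypoxia, slow muscle, nuclear oxidative phosphorylation and ribosomal protein lists were called as higher without exposed replicate 1 (adjusted p = 0.0121, 0.00294, 0.00403 and 0.000316). Without control replicate 1, hypoxia (0.0401), nuclear oxidative phosphorylation (0.00358), ribosomal proteins (0.000981) and epidermis (0.0177) were called. So were, without exposed replicate 3 fatty acid oxidation (0.00335) and the xenobiotic response (0.0039), and without control replicate 3 DNA repair (0.0488) and, in the other direction, ribosomal proteins (0.033). In all 5 comparisons tested with camera, 0 list calls held with an estimated correlation. That test gave 5, 3, 2, 4 and 6 lists at an unadjusted p under 0.05 for the exposure at 7 dpf, at 10 dpf, the difference between ages, and the changes with age in control and in exposed larvae. In that order camera with its preset correlation called 20, 22, 17, 19 and 27 and fry 2, 10, 0, 19 and 23. In the list means at 10 dpf exposed and control libraries overlapped for pancreas, liver, intestine, yolk, antioxidant, myogenesis, hormone and pigment cell genes, and not for the other lists called. For the difference, where fry gave 0, it had 3 at an unadjusted p under 0.05.

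**Figure D3:**
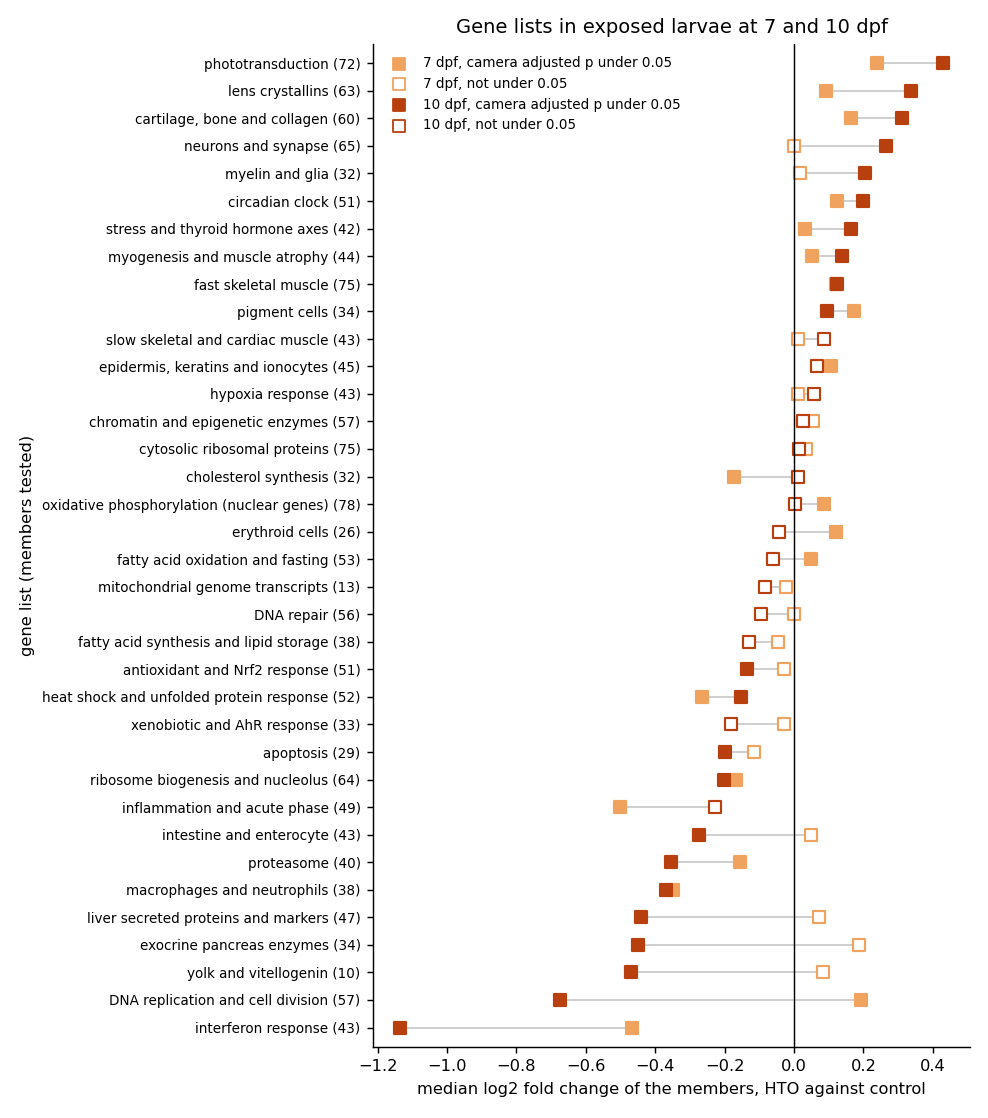
Median log2 fold change of exposed against control larvae over the tested members of each gene list reported here, light squares for 7 dpf and dark squares for 10 dpf, filled where the camera adjusted p was under 0.05. Phototransduction lies highest at 10 dpf with 0.43 and the interferon response lowest with -1.13.

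The lists of genes called at the 2 ages were then compared, to ask whether the same genes changed. They shared 81 genes, where 14.0 would fall together if calls were independent, and 78 of these moved in the same direction: 23 were higher at both ages (1.96 by chance) and 55 lower (5.48 by chance). Opposite changes were found in si:ch73-335l21.4 (-1.19 at 7 dpf, 0.42 at 10 dpf), CYP26B1, which degrades retinoic acid (-0.44 and 0.40), and JUN (-0.39 and 0.25). Over all genes the fold changes at both ages correlated with r = 0.502 and rho = 0.338 (covariance 0.105), across genes that are not independent replicates, and the comparisons share no library. Control replicates of the same number resembled each other between the ages in their deviations from the group mean (r of 0.0431 to 0.224). The comparisons may therefore not be independent. Of the 119 genes called at 7 dpf, 110 (92.4%) had the same sign at 10 dpf. The following shared genes were chosen after their values were seen, and no list or enrichment test was made for them. Falls were those of the transducer STAT3 (-0.85 at 7 dpf and -0.62 at 10 dpf), the kinase TYK2 (-0.60 and -0.49), the receptor gene il23r (-1.33 and -1.38), the cytokine subunit il12b2 (-2.58 and -2.71) and il17ra1a (-0.86 and -1.05). The cytokine gene il17a/f1 had 0 reads in the 3 exposed libraries at 7 dpf and 0, 1 and 0 at 10 dpf, against 88, 52 and 10, and 23, 13 and 14 reads in controls. The macrophage gene cd68 (-0.72 and -1.22), ELF3 (-2.12 and -1.64) and cldnf (-1.01 and -0.93) were likewise lower, and smtlb (1.59 and 1.82) and gch2 (0.75 and 1.25) higher at both ages. Each of these genes lost its 7 dpf call on leaving out control replicate 1, with adjusted p from 0.0502 for gch2 and smtlb to 0.214 for cd68. So did CYP26B1 (0.152) and JUN (0.189), both also without every other library except control replicate 3, and JUN kept its 10 dpf call in none of the 6 runs that left out a library (up to 0.136). At 10 dpf il17a/f1 lost its call without exposed replicates 2 and 3 or control replicate 1 (up to 0.0726). The count of 78 ranged from 3 without control replicate 1 at 7 dpf to 546 without control replicate 3. It was 13, 21 and 17 without exposed replicates 1, 2 and 3 at 7 dpf, and 10 without control replicate 2 at 7 dpf. It was 48 without exposed replicate 2 at 10 dpf, and 33, 35 and 39 without control replicates 1, 2 and 3 at 10 dpf.

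**Figure D4:**
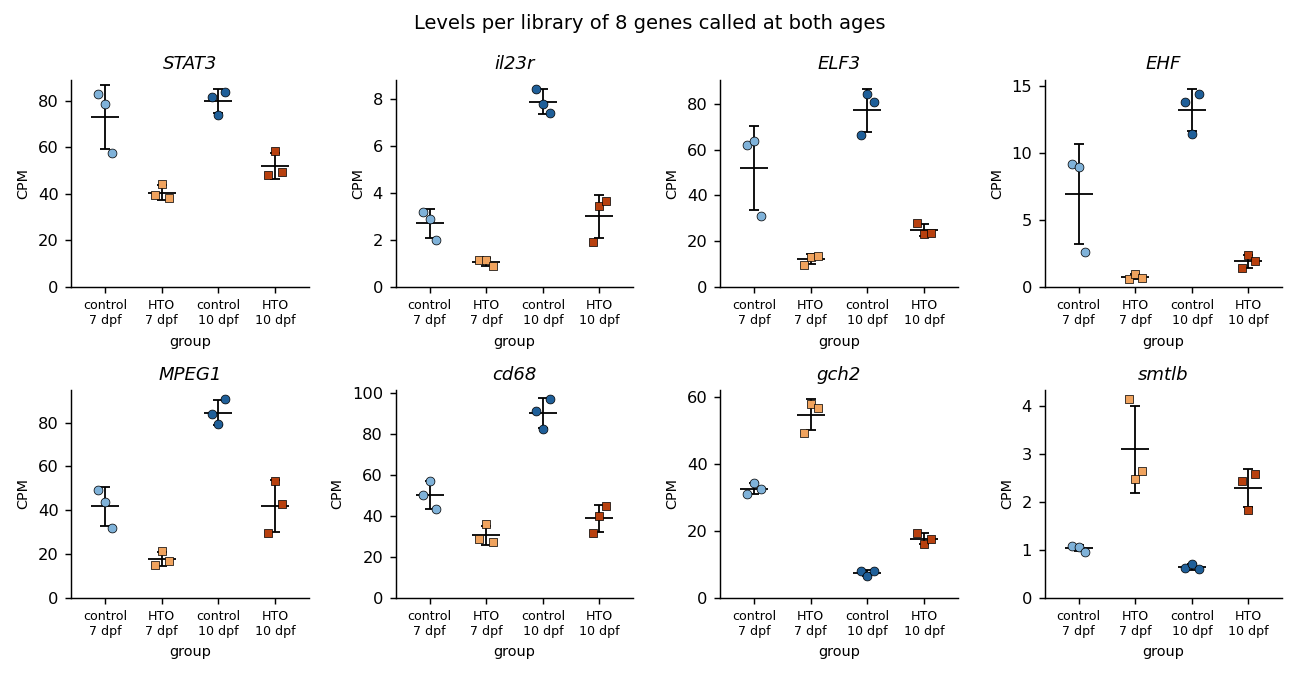
Levels in CPM of 8 genes called at both ages, chosen after their values were seen, with a point for each library and bars for the mean ± SD (n = 3) of each group. STAT3, il23r, ELF3, EHF, MPEG1 and cd68 were lower in exposed larvae at both ages, as for EHF with 0.744 against 6.90 CPM at 7 dpf, and gch2 and smtlb were higher.

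Whether the response itself differed between the ages was tested as the difference of both effects. The dose taken up by each age is not given here and may be larger at 10 dpf. Age and dose are therefore not separated in this difference. It passed in 62 of 23075 genes, 24 with a higher and 38 with a lower value at 10 than at 7 dpf. The genes named are those with the smallest p among genes with a mean of at least 5 CPM in 1 group. These were si:ch73-335l21.4 (1.602), ponzr4 (2.72), rtn4rl2a of the Nogo receptor family (1.39) and FUCA1 (-1.18), each with adjusted p = 0.00297. KLHL24 (-0.89, adjusted p = 0.00502) came next. The level of rtn4rl2a was 44.3 CPM in controls and 38.4 in exposed larvae at 7 dpf, and 18.5 and 42.1 at 10 dpf. That of KLHL24 was 171.5 and 189.5 CPM at 7 dpf and 276 and 165 at 10 dpf. These 5 kept their call whichever library was left out. DNA replication and cell division genes differed most as a list (median -0.86, camera adjusted p = 7.12e-27, adjusted p = 0.606 with an estimated correlation). Of its members 5 were lower at 10 dpf relative to 7 dpf (kif11 -1.69, TOP2A -1.50, mki67 -1.20, TPX2 -1.19 and CDC20 -1.004, named after their values were seen) and 37 adjusted over the list alone. The number of 5 was 0 without exposed replicates 1 and 3 or control replicate 2 at 7 dpf, and 10 without control replicate 1 at 7 dpf. The count of 62 was 10, 24 and 14 without exposed replicates 1, 2 and 3 at 7 dpf, and 12 and 39 without control replicates 2 and 3 at 7 dpf. It was 41, 27 and 30 without exposed replicates 1, 2 and 3 at 10 dpf, and 17 and 24 without control replicates 1 and 2 at 10 dpf.

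Between 7 and 10 dpf 6770 genes changed in control larvae, 3300 up and 3470 down. The hypertrophic cartilage collagen COL10A1 (ENSDARG00000054753) fell from 153 to 10.18 CPM (-3.92, adjusted p = 3.4e-06) and the red cone opsin opn1lw2 (ENSDARG00000044861) from 124 to 8.32 CPM (-3.89, adjusted p = 3.5e-07). NOS2, the inducible nitric oxide synthase, rose from 0.369 to 11.3 CPM (4.91, adjusted p = 1.93e-05), and MFAP4 by 3.12. Further large falls were those of the keratins krt1-19e (-3.64) and cyt1l (-3.36), the enamel matrix gene enam (-3.21) and TIMP2 (-3.47), and further rises those of lgals9l4 (5.25), rnasel4 (4.08), P2RX4 (3.85) and MYH11 (3.82). TIMP2 lost its call without control replicate 1 at 7 dpf (-0.40, adjusted p = 0.0528) or any control replicate at 10 dpf (adjusted p up to 0.126).

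Of the 37 lists, 19 were called with age in controls, and 0 with an estimated correlation. Cartilage, bone and collagen genes fell in 48 of 60 cases, 49 adjusted over the list alone (median -1.48, adjusted p = 2.52e-29, 0.0628 with an estimated correlation), such as LUM (-2.10) and POSTN (-1.84). In contrast, 73 of 75 ribosomal protein genes rose, 74 adjusted over the list alone (0.48, adjusted p = 8.33e-24, 0.388 with an estimated correlation). Falls prevailed in phototransduction (52 of 72, adjusted p = 1.4e-21), fast muscle (45 of 75, 9.38e-18), DNA replication (47 of 57, 9.28e-16), nuclear oxidative phosphorylation (42 of 78, 3.33e-12), and neurons (35 of 65, 1.08e-10). They also did in slow muscle (20 of 43, 1.24e-06), myelin and glia (18 of 32, 4.05e-06), erythroid cells (13 of 26, 1.97e-05), the mitochondrial genome (9 of 13, 0.000108), pigment cells (15 of 34, 0.000226), cholesterol synthesis (10 of 32, 0.000326), myogenesis (16 of 44, 0.0127) and hypoxia (16 of 43, 0.0361). Adjusted over the list alone these counts were 58, 51, 49, 47, 41, 22, 19, 17, 10, 15, 14, 17 and 19. In the same order the adjusted p with an estimated correlation were 0.263, 0.263, 0.388, 0.491, 0.41, 0.388, 0.082, 0.388, 0.388, 0.388, 0.615, 0.388 and 0.388. Rises prevailed in the proteasome (32 of 40, adjusted p = 3.18e-13), ribosome biogenesis (34 of 64, 1.17e-09), the interferon response (11 of 43, 0.000259) and macrophages and neutrophils (10 of 38, 0.00244). The counts were 34, 35, 11 and 10 adjusted over the list alone and adjusted p of 0.388, 0.51, 0.671 and 0.767 with an estimated correlation. Runs that left out a library gave 8 to 19 rises for the interferon list, 5 to 14 for macrophages, and 8 to 13, 5 to 9 and 4 to 14 falls for erythroid cells, the mitochondrial genome and cholesterol synthesis. Inflammation was not called (7 rises and 9 falls, adjusted p = 0.636). The hypoxia call was lost with the stricter filter (0.0504), without control replicate 1 at 7 dpf (0.13) or control replicate 2 at 10 dpf (0.0553), and that of macrophages without control replicate 3 at 7 dpf (0.0713).

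In exposed larvae 5343 genes changed between the ages, 2490 up and 2853 down. These changes may hold those of a longer exposure as well as those of age. Of the same genes as in controls, krt1-19e (-3.26), enam (-3.20), COL10A1 (-3.19) and opn1lw2 (-3.10) fell, together with the ubiquitin-like gene isg15 of the interferon response (-2.90) and the transglutaminase TGM2 (-2.78). In the interferon response list 6 genes rose and 1 fell with age in exposed larvae. The urea transporter SLC14A2 (2.90), clca1 (2.72), vwa10.1 (2.46), il22ra2, a soluble receptor of interleukin 22 (2.18), tmem269 (1.96) and plekhs1.1 (1.95) rose. DNA replication genes fell in 53 of 57 cases, 56 adjusted over the list alone (median -1.69, adjusted p = 6.87e-34, 0.197 with an estimated correlation), with NUSAP1 (-2.59 against -1.67 in controls) and TPX2 (-2.27). Cartilage, bone and collagen fell in 47 of 60, 49 adjusted over the list alone (-1.26, adjusted p = 4.69e-31, 0.0509 with an estimated correlation). Of 63 lens genes 24 rose and 5 fell, 25 and 6 adjusted over the list alone (0.24, adjusted p = 4.46e-05, 0.532 with an estimated correlation). The rises were 16 without exposed replicate 3 at 7 dpf, and 1 fell without exposed replicate 1 at 7 dpf or 2 at 10 dpf. Of 49 inflammation genes 14 rose, 15 adjusted over the list alone (0.25, adjusted p = 0.00263, 0.509 with an estimated correlation). In all, 27 lists were called. The 10 of them not called in controls were lens, inflammation, the antioxidant response (down, adjusted p = 0.00066), heat shock (up, 0.0476), pancreas (down, 0.0188), intestine (down, 0.000197), liver (down, 1.99e-06), fatty acid oxidation (down, 0.000152), epidermis (down, 0.0324) and yolk (down, 0.00143). For the last 8 of these the adjusted p with an estimated correlation were 0.509, 0.708, 0.69, 0.496, 0.591, 0.496, 0.488 and 0.488. Without exposed replicate 1 at 10 dpf the pancreas list turned upward (0.0205), cholesterol synthesis was not called (0.141) and the interferon response was (0.0392, with 7 rises and 1 fall). Heat shock was not called without exposed replicates 1 and 3 at 7 dpf (0.104 and 0.0676) or 2 and 3 at 10 dpf (0.0839 and 0.206), and neurons were not called without the same libraries (0.111, 0.131, 0.0629 and 0.318). Heat shock also lost its call with upper quartile scaling (0.0507), the stricter filter (0.0836) and unstranded counts (0.0575). Macrophages were not called without exposed replicate 3 at 10 dpf (0.201) and epidermis without exposed replicate 2 at 7 dpf (0.112). The call of isg15 was lost without exposed replicate 2 at 10 dpf (adjusted p = 0.0583), and that of vwa10.1 without exposed replicates 1 and 3 at 7 dpf or 2 and 3 at 10 dpf (up to 0.0712).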

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

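In this part the 3 tests of the library short of digestive transcripts were chosen only after the result was seen. The differences of the effect are given because genes and lists passed the tests of a difference between 7 and 10 dpf, for which chance is not excluded. The shares of reads are given because the comparisons do not use these reads. The digestive lists of 1 library are given since 3 of the lists that differed are those of digestive organs.

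The effect of exposure differed between the ages in 62 genes, a count that was 10 without exposed replicate 1 at 7 dpf and 12 without control replicate 2 at 7 dpf. The effect at 10 dpf minus that at 7 dpf was above 0 for si:ch73-335l21.4 (1.602, from -1.19 to 0.42), ponzr4 (2.72) and rtn4rl2a (1.39), and below 0 for FUCA1 (-1.18) and KLHL24 (-0.89). Among lists, the median difference was -0.86 for DNA replication and cell division, -0.63 for exocrine pancreas, -0.55 for yolk, -0.40 for the interferon response, -0.40 for liver, -0.19 for the proteasome, -0.145 for fatty acid oxidation, -0.12 for intestine, -0.10 for DNA repair and -0.0927 for the antioxidant response. It was 0.40 for inflammation, 0.29 for neurons, 0.26 for lens, 0.21 for phototransduction, 0.20 for cartilage and bone, 0.18 for myelin and glia and 0.077 for clock genes. None of these 17 camera calls held with an estimated correlation, where 2 lists had an unadjusted p under 0.05. With fry 0 lists passed, with 3 at an unadjusted p under 0.05. Without exposed replicate 1 at 10 dpf the calls were lost for the antioxidant response (adjusted p = 0.23), liver (0.694), fatty acid oxidation (0.184), cartilage (0.0896) and yolk (0.0896). The intestine list lost its call there too, with a direction of up (0.554). The interferon call was lost without control replicate 3 at 7 dpf (0.0891), that of clock genes without 5 of the 12 libraries (up to 0.192 without control replicate 3 at 7 dpf), with RLE (0.0589) and with the stricter filter (0.0691), and that of DNA repair without 5 (up to 0.117 without exposed replicate 3 at 10 dpf). That of intestine was lost without 5 (also 0.097 without exposed replicate 2 and 0.124 without control replicate 3 at 7 dpf, 0.0878 and 0.0682 without control replicates 2 and 3 at 10 dpf). Of 100 splits drawn from the 200 that exchange libraries within an age, 7 gave as many genes, the real one with 62 included, and the highest other gave 3644. All 6 others keep the real groups at 10 dpf, which puts the effect at that age into the difference by construction. Chance is not excluded for this count, and these splits do not decide on it. For the other comparisons 1 of 10 splits gave as many genes, the real one, with 119, 2721, 6770 and 5343 genes against 0 in the highest other by edgeR, and 10 splits are too few for a share under 0.05.

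The share of reads that did not map was 4.80% in exposed and 4.57% in control larvae at 7 dpf and 4.84% against 5.25% at 10 dpf, and the difference of 0.643 between these effects was not tested. Reads that mapped to several places took 14.74% in exposed and 14.52% in control larvae at 7 dpf, and 14.52% in both at 10 dpf. No biological explanation was tested for these shares.

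In exposed replicate 1 at 10 dpf 74.19% of the members of the pancreas, liver and intestine lists were over 2-fold lower than in the rest of its group. Depth is argued against by -0.1647 in the shallowest library of the series, and a swap within the series by 0.2033 as the largest deviation in the other groups. Less digestive tissue in that sample may account for it, and whether this came from feeding state, collection or exposure stays open.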

How the results depend on the processing

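In this part the stratified exact test and the thinning were chosen only after the result was seen, and other alternatives were planned. At 7 dpf the 119 genes became 62 with the replicate block, 66 with the compared groups alone, 447 with voom and sample weights, 595 with DESeq2 and 0 against a fold of 1.5 with glmTreat, which gave 497 at an unadjusted p under 0.05. All 119 were among those of DESeq2 and of voom. On simulated data at 7 dpf DESeq2 made 27 false calls, against 4 each for edgeR and voom. Those counts were drawn with edgeR's own estimates of the spread and with independent genes. They therefore do not rank the tools on the real data. At 10 dpf the fold test left 211, for the ages 993 in controls and 684 in exposed larvae. The difference had 22 genes with the replicate block, 2 against the fold, 152 with voom and 280 with DESeq2, and the genes changed alike at both ages were 37 with the block and 22 with the compared groups alone. Replicate numbers did not pair exposed with control libraries, with r of -0.158 to 0.065 at 7 dpf. Between the control groups of the 2 ages each replicate matched its own number best, with r of 0.224, 0.0431 and 0.183. No label says whether control libraries with the same number share an origin, so these groups may not be independent. Leaving out 1 library gave 12 to 831 genes at 7 dpf, 1153 to 2145 at 10 dpf, 10 to 63 for the difference, 5044 to 6268 and 3722 to 5233 for the ages and 3 to 546 alike at both ages. List calls ranged from 17 to 22, 17 to 24, 14 to 22, 18 to 20 and 25 to 28. An estimated correlation left 0 camera calls in each comparison, with 5, 3, 2, 4 and 6 at an unadjusted p under 0.05, and fry gave 2, 10, 0, 19 and 23. Without exposed replicate 1 at 10 dpf, liver (adjusted p = 0.5943) and intestine (0.4737) at 10 dpf and intestine for the difference (0.5539) lost their calls and changed sign. Pancreas with age in exposed larvae was then called in the other direction (0.02055). In this order these results had 3.11e-11, 0.0002254, 0.0001681 and 5.363e-05 without exposed replicate 3 at 10 dpf, and the last had 0.03924 without exposed replicate 2 at 7 dpf. The age shift was -0.3125 to -0.1909 at 7 dpf and -0.3817 to -0.222 at 10 dpf without 1 library, and -0.1166 and -0.1826 from 500 genes. The causes of lower and higher counts without single libraries were not tested. Reads of 19.4 M in the shallowest library limit genes near the floor.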

Other observations

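In this part the clock test, the test of a lag shared by all lists, the tests of the interferon and macrophage lists without 1 control library, the test of fewer macrophages and neutrophils, the stratified exact test, the thinning of all libraries, and NOS2, CYP26B1 and gata1a were chosen only after the result was seen. Inducible nitric oxide synthase NOS2 reached 11.3 CPM in controls at 10 dpf and 2.56 CPM in exposed larvae (-2.10, adjusted p = 0.00473). The retinoic acid hydroxylase CYP26B1 went from 52.7 to 38.9 CPM with exposure at 7 dpf and from 31.4 to 41.6 CPM at 10 dpf. The erythroid regulator gata1a fell at 10 dpf (-2.63, adjusted p = 0.00624) while the erythroid list as a whole was not called.

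Changes with exposure were compared with the mean change from 7 to 10 dpf over control and exposed larvae, into which both groups enter alike. Of the 119 genes called at 7 dpf 108 (90.8%) moved against it, 35 as rises of genes that fall with age and 73 as falls of genes that rise, and of the 2721 called at 10 dpf 2178 (80.0%) did, 874 and 1304 of them. Of all tested genes 59.7% and 58.9% did, and no test was made of these shares. At 10 dpf the cell division genes were among the exceptions.

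Exposed larvae lay earlier on the axis of the age change, at -0.1225 ± 0.0772 against 0.1225 ± 0.0694 in controls at 7 dpf and at 0.828 ± 0.0644 against 1.17 ± 0.0205 at 10 dpf. The shifts of -0.245 and -0.344 each have an exact p of 0.1, the smallest that 20 relabellings give, and their mean of -0.294 a stratified exact p of 0.005, the smallest of 400. The 400 relabellings take the ages as independent. Control replicates of the same number resembled each other between the ages, so the p of 0.005 may be too small. The shifts were -0.1166 and -0.1826 with 500 genes, and the one at 10 dpf was -0.222 without exposed replicate 3. Depth as the whole cause is argued against by the shift of -0.2726 after thinning, and the library short of digestive transcripts by -0.3663 at 10 dpf without it. A lag that moved all age-dependent lists alike would raise DNA replication genes, which fall with age, but they lay at -0.6159 at 10 dpf. It would also lower ribosomal protein genes, of which 71 rose with age in exposed larvae. With exposure at 10 dpf 0 of these genes passed, and the direction of their list changed with the library left out. The erythroid, mitochondrial genome and nuclear oxidative phosphorylation lists, which fall with age, were not called at 10 dpf with all libraries. Phototransduction and cartilage lists, which also fall with age, were higher. A delay of part of the age program may remain, and the separate incubator of the exposed larvae stays open.

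The macrophage and interferon lists were lower in exposed larvae at both ages and the inflammation list at 7 dpf (adjusted p = 0.288 at 10 dpf), by camera with its preset correlation, and none of them with an estimated correlation. At 7 dpf the means of the interferon and macrophage lists overlapped between exposed and control libraries. Control replicate 1 at 7 dpf as the only source of the inflammation result is argued against by an adjusted p of 1.44e-11 for that list at 7 dpf without it, where 3 members passed, against 7 with it. For the other lists this stays open, since their libraries overlap, with an adjusted p of 0.05988 and a median of -0.12 for interferon and 0.03982 and -0.16 for macrophages without that library. The count of genes at 7 dpf went from 119 to 12 without it. All 78 genes called lower stayed lower, at a median of -1.10 against -1.25, which was measured on genes chosen for their fall. STAT3 went from -0.85 ± 0.126 to -0.73 ± 0.13 (log2 change ± SE), il23r from -1.32 ± 0.244 to -1.14 ± 0.266, il12b2 from -2.58 ± 0.377 to -2.27 ± 0.401 and cd68 from -0.72 ± 0.142 to -0.70 ± 0.166. Their calls were lost with a slightly smaller change and a larger SE. Fewer macrophages and neutrophils may be the cause or not: the upper quartile at 10 dpf of the 78 genes called lower at 7 dpf was -0.5295, with a median of -0.91, against a median of -0.37 and a lower quartile of -0.59 in the leukocyte list, where 32 of 38 genes were lower. Cell number and signalling per cell cannot be told apart in RNA of entire larvae.

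A candidate explanation for the higher clock list is another phase of the clock at sampling. At 10 dpf the 16 genes of the repressor arm had a median of 0.43, with 11 rises, and the 6 genes of the activator arm -0.29, with 2 falls, bmal2 (-0.78) and CLOCK (-0.37). The call of CLOCK was lost without exposed replicate 3 or control replicate 3 (adjusted p up to 0.093). The arms moved in opposite directions and differed by -0.7167. At 7 dpf the medians were 0.26 in the repressor arm, with 16 of 16 genes above 0, and -0.11 in the activator arm. Another phase could give a difference of either sign, and the arms could move apart without one, so these values do not decide on it. Sampling times and light in each incubator are not given in the sources used here, so a shift of phase through the incubator stays as open as one through exposure.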
